A study of Mus musculus with 2 samples.

How the data were processed

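Chromatin accessibility was measured by DNase-seq in midbrain tissue of mouse embryos of the B6NCrl strain at embryonic day 10.5. DNase I cuts open chromatin, and the sequenced ends of the released fragments mark the cuts. The series holds 1 group of 2 samples, which the labels call biological replicates 1 and 2. Each came from pooled male and female embryos, and both carry the same donor label, so the spread between them measures 2 tissue collections at most. The label of replicate 2 names 2 sequencing instruments, a NextSeq 500 and a HiSeq 4000, and that of replicate 1 names none. With 1 group there is no comparison between groups. The comparisons made are those between the replicates, between gene lists and all other genes, between peaks and their flanks, and between footprints and shifted positions.

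The files were aligned to mm10 per the labels, which is the GRCm38 assembly used here for sequence and annotation. All 21 chromosomes of each interval file matched the assembly by name, and 0 intervals ran past a chromosome end. Each sample had its own calls, with no pooling of replicates per the deposited file lists. These lists name 2 alignments per sample. The 150 bp peaks, the hotspots and one cut-rate file came from the first, and the variable-width peaks, the footprints and the other cut-rate file came from the second. The aligner, the peak caller, its version and its threshold are not given in the sources used here.

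The peak lists deposited by the authors give a signal value per peak. In the 150 bp list this signal is a whole number of at least 1 with no stated normalization, and it is called the peak score below. There were also a longer and a shorter variable-width list. In the longer list the deposited signal values were whole multiples of 1 step per sample, 0.00443 in replicate 1 and 0.00395 in replicate 2. This held for 100% of values within 0.05 of a whole multiple. The shorter list was not examined for this. Such steps would arise from scaling to depth, and their ratio was 1.12 for replicate 2 over replicate 1. The depth itself is not given in the sources used here, so intervals below cover counting of peaks or genes only. Hotspots, wider stretches with an excess of cuts, carry a −log10 q-value per the broadPeak format named in the deposited file lists, capped at 100, and a deposited score that is 10 times that value cut to a whole number. The cut-rate files deposited by the authors list stretches of positions with a q-value (false discovery rate) of at most 0.05. Footprints, short stretches protected from cutting within open chromatin, carry the same deposited value of 0.01 throughout, whose meaning is not stated. Scores were used to rank or filter peaks within a list. Ratios of scores within a list, and correlations of scores across shared peaks, are given as descriptions, since the normalization is not stated.

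Genes were taken from GENCODE release 21 for mouse. It gave 21815 protein-coding genes with 41408 transcription start sites (TSSs). Each gene was given 1 main TSS, that of its principal transcript by APPRIS tag, or of the longest where several ranked alike. A promoter was called open where a 150 bp peak of both replicates overlapped the region of the main TSS by at least 1 bp within 500 bp on either side. A peak was TSS-proximal where its midpoint lay within 1000 bp of a protein-coding TSS, and distal otherwise. Distal peaks were counted within 50 kb of each TSS. The 20 gene lists held 373 different genes, of which 372 matched the annotation (Ahsp did not). The share of open promoters in each list was set against all other protein-coding genes with a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 20 lists. A two-sided exact test within tertiles of promoter CpG ratio was the alternative. The median number of distal peaks of a list, as the mean of both replicates, was set against 10000 random lists of the same size, drawn with seed 20 and matched on the number of TSSs within 50 kb and on CpG ratio. Genes are not replicates, so these p-values and percentiles describe these libraries.

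For sequence, 30 IUPAC consensuses of known transcription factor classes were searched on both strands in 150 bp windows of distal peaks shared by both replicates, and in equal windows 500 bp to either side outside peaks and hotspots. The shares were compared with a two-sided Fisher's exact test and adjusted over the 30 consensuses. Footprints were compared in the same way, in 25 bp windows, with positions shifted by 50 bp inside the same peaks. Overlaps were set against 100 random placements. Intervals on shares are 95% Wilson intervals.

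The gene lists, the consensuses, the tests and the first set of alternatives were fixed before the data were examined. The genes named are the 3 members of each list with the most distal peaks, the first 2 members by symbol that go against their list at the promoter, and Otx2, En1, En2, Pax2, Wnt1, Fgf8, Lmx1a, Foxa2, Sox2, Neurog2, Hoxa2, Gata1, Alb, Myod1 and Actb. Some genes that this rule takes are not reported here. The alternatives fixed beforehand were the other peak lists, equal numbers of peaks, hotspots in place of peaks, 50% reciprocal overlap, TSS windows of 500 bp and 2 kb, promoters of 1000 bp on either side, CpG tertiles, distal windows of 20 kb and 100 kb, no matching, sequence windows of 100 bp and 200 bp, flanks matched on GC content, footprints inside shared peaks, autosomes only and each replicate left out. The alternatives chosen after seeing the data were the removal of dense weak peaks, CpG-poor distal peaks only, 1 member per locus, the posterior Hox promoter test with 1 replicate alone, a peak at any annotated TSS of a gene, sequence windows and peaks without a CTCF consensus, dense weak peaks beside other peaks of the same score, GC content over the 150 bp of a peak in place of 500 bp, the second alignment of the cut-rate files and a cut-rate FDR of at most 0.001.

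The steps were tested on simulated data. Of 200 unchanged lists of 20 genes among the 21815 genes, the promoter test called 4%, and it called 100% of lists drawn with an open share of 15%. The distal test placed 5% of 100 random lists outside the 95% range, and 100% of lists whose counts were raised 3 times plus 3 above it. A CTCF consensus planted in 800 of 4000 random windows was found in 801 of them, and 1 of the 29 other consensuses was called there (ZIC/GLI, where 195 of the 197 windows with a match had it overlapping the planted site). The overlap function and bedtools differed for 0 of 3000 intervals. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with bedtools 2.31.1 for reciprocal overlaps and for pairing the peaks of the replicates.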

Results

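Open chromatin of the mouse midbrain was mapped by DNase-seq at embryonic day 10.5, when the midbrain is a neural tube patterned from the isthmus, the signalling centre at its border with the hindbrain. The data were 1 group of 2 biological replicates, each from pooled embryos. Replicate 1 held 122475 peaks and replicate 2 held 140470, a ratio of 1.15, and 99.2% and 99.7% of them were exactly 150 bp wide. The peaks covered 18.3 and 21.1 Mb of the genome. Hotspots numbered 93006 and 115852 and covered 53.6 and 55.7 Mb, and footprints numbered 339296 and 382934. Read depth was unknown, but steps in the deposited signal values gave a relative depth of 1.12 for replicate 2 over replicate 1, if they arose from scaling to depth, beside the ratio of 1.15 in peaks.

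The first comparison asked whether genes that pattern the midbrain lay in open chromatin more often than other genes. Each gene's promoter was taken at 1 main TSS. Of 20 midbrain and isthmus patterning genes, 19 had a promoter peak in both replicates, against 62.7% of other protein-coding genes (odds ratio 11.3, 95% interval 1.51 to 84.4, adjusted p = 0.00303, two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 20 lists). Within promoters of like CpG ratio the odds ratio was 27.1 but the call was lost (adjusted p = 0.145, exact test within CpG tertiles), with 98.7% of all promoters open in the CpG-richest tertile. The odds ratio was 3.63 with the shorter variable-width peak list (adjusted p = 0.0486, Fisher's exact test). With a peak at any annotated TSS of the gene counted, an alternative added after seeing the data, all 20 were open (odds ratio 21.9, adjusted p = 0.00051, Fisher's exact test). The exact test within CpG tertiles of the main TSSs gave adjusted p = 0.0186. Cnpy1, the member gained, was open at another TSS, whose CpG ratio these tertiles do not hold. Distal peaks crowded around the same list. Its median member had 27 distal peaks within 50 kb of the TSS as the mean of both replicates, above all 10000 matched random lists, 95% of which had medians from 2.25 to 6.75. The median over all 21815 genes was 4.

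The members with the most distal peaks were Dmbx1, a homeobox gene of the early midbrain (chromosome 4, 115915119 to 115939926, GRCm38), with 54 and 37 in replicates 1 and 2, Lmx1b with 46 and 45, and En2 (chromosome 5, 28165694 to 28172166) with 49 and 38. En1, which with En2 sets midbrain and anterior hindbrain identity, had 38 and 34. Otx2, which marks the forebrain and midbrain in front of the isthmus (chromosome 14, 48657677 to 48673819), had 33 and 23. Pax2 had 42 and 41, and Wnt1, expressed at the isthmus, had 37 and 33. Fgf8, the signal released by the isthmus (chromosome 19, 45736798 to 45742915), had 32 in replicate 1 and 13 in replicate 2. Cnpy1 was the 1 member with no peak at its main TSS in either replicate, although another of its TSSs had one in both, and it had 8 distal peaks in each.

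Genes of the floor plate and dopaminergic lineage had open promoters in 16 of 19 cases (adjusted p = 0.0783, Fisher's exact test) and a median of 19.5 distal peaks, above all random lists. The regulators among them, Msx1 with 30 and 34 distal peaks, Foxa2 with 34 and 22 and Lmx1a with 14 and 18, had promoter peaks in both replicates. The enzyme genes Ddc, of dopamine synthesis, and Aldh1a1 had none at their main TSSs (another TSS of Aldh1a1 had one in replicate 2), with 17 and 12 distal peaks around Ddc and 2 in each replicate around Aldh1a1. All 22 regulators of ventral and dorsal midbrain neurons had open promoters (adjusted p = 0.000297, Fisher's exact test; 0.289 within CpG tertiles) and their median was 24.25 distal peaks. Pax3 (50 and 60) and Pax7 (59 and 43) led this list.

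Neural progenitor genes had open promoters in 23 of 24 cases (odds ratio 13.7, adjusted p = 0.001, Fisher's exact test) and a median of 25.25 distal peaks. Zic1 had 60 and 66, Sox2, a factor of neural stem cells, had 55 and 52, and Pax6 had 48 and 52. After removal of dense weak peaks, an alternative added after seeing the data, Pax6 had 48 and 44. Within CpG tertiles the odds ratio of this list rose to 39.1 while its call was lost (adjusted p = 0.0811, exact test). The exception, Hes3, carried a peak at its main TSS in replicate 2 alone and at another TSS in both. With any annotated TSS all 24 were open (adjusted p = 0.00962, exact test within CpG tertiles of the main TSSs). Those tertiles do not hold the CpG ratio of the other TSS of Hes3. Neuronal differentiation genes had a lower median of 10 distal peaks, still above all random lists, and 19 of 23 open promoters. Their promoter test missed the threshold against all genes (adjusted p = 0.0756, Fisher's exact test) and passed it within CpG tertiles (odds ratio 15.3, adjusted p = 0.0148) and with any annotated TSS, where 21 were open (odds ratio 5.62, adjusted p = 0.0113, Fisher's exact test). Dcx and Myt1, both switched on in young neurons, had peaks at their main TSSs in replicate 2 alone, and Myt1 had one at another TSS in both. Nhlh1 (43 and 29) and Onecut1 (38 and 30) had the most distal peaks there after both replicates were averaged, followed by Ebf1 (24 and 37), and the proneural gene Neurog2 had 19 and 18. After removal of dense weak peaks, Nhlh1 had 36 and 29 and Ebf1 had 24 and 21. Targets of FGF, WNT, SHH and Notch signalling had 19 of 20 open promoters (adjusted p = 0.00303, Fisher's exact test; 1 within CpG tertiles) and a median of 13.25 distal peaks, led by Axin2 (36 and 23) and Lfng (30 and 21). Sp8 had no promoter peak in either replicate.

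Regulators of other body regions had many distal peaks, and their promoters differed from list to list. All 21 forebrain regulators had open promoters (adjusted p = 0.000314, Fisher's exact test; 0.200 within CpG tertiles), and their median was 29 distal peaks. Dlx6 (51 and 47), Dlx5 (50 and 49) and Six3 (47 and 32) led them. Posterior Hox genes, which pattern the trunk and limbs, had the highest median of the 20 lists, 43.5 distal peaks. The list sits in 4 clusters, and with 1 member per locus, an alternative added after seeing the data, 4 genes remained with a median of 44.75. Their promoters were open in 8 of 16 cases (adjusted p = 0.364, Fisher's exact test), fewer than CpG-like promoters (odds ratio 0.123, adjusted p = 2.20e-05, exact test within CpG tertiles). That call rested on replicate 1, where 8 of the 16 promoters had a peak. Replicate 2 had a peak at 14 of them, and in replicate 2 alone, a test added after seeing the data, the odds ratio was 0.568 (adjusted p = 0.458, exact test within CpG tertiles). Anterior Hox and hindbrain regulators had a median of 23.5 distal peaks and 11 of 15 open promoters (adjusted p = 0.660, Fisher's exact test), with no peak in either replicate at any annotated TSS of Hoxa3 or Hoxb3.

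The replicates differed at the HoxA and HoxD clusters by more than in their total number of peaks. Replicate 2 had 103 peaks across the HoxD cluster (chromosome 2, 74668310 to 74765142) and replicate 1 had 54, a ratio of 1.91, beside 1.15 for all peaks. The HoxA cluster had 65 against 33, a ratio of 1.97. HoxB and HoxC went the other way in this list, with 73 against 82 and 64 against 80 peaks in replicates 2 and 1. For HoxC this did not hold in the longer variable-width list (62 against 61) or for footprints (175 against 142), but it held for hotspots (50 against 66). HoxB had 51 against 47 hotspots, but fewer peaks in the longer list (73 against 82) and fewer footprints (211 against 258). Over the genome the ratio of replicate 2 to replicate 1 was 1.21 for the longer list, 1.25 for hotspots and 1.13 for footprints. Hoxd9 had 42 distal peaks in replicate 1 and 76 in replicate 2, Hoxd3 had 38 and 76, and Hoxa2, expressed in the hindbrain, had 29 and 49. After removal of dense weak peaks, an alternative added after seeing the data, Hoxa2 had 29 and 40, while Hoxd9 and Hoxd3 kept their counts. Single genes away from the Hox clusters differed as much, also after this removal. Gata4 had 70 and 31 distal peaks and Fgf8 32 and 13, with more in replicate 1. Foxa3 had 5 and 14, with more in replicate 2. The spread of the replicate ratio over other loci was not measured, so the differences cannot be called particular to Hox genes. With 2 samples of 1 group, no test of these differences was possible.

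**Figure D1:**
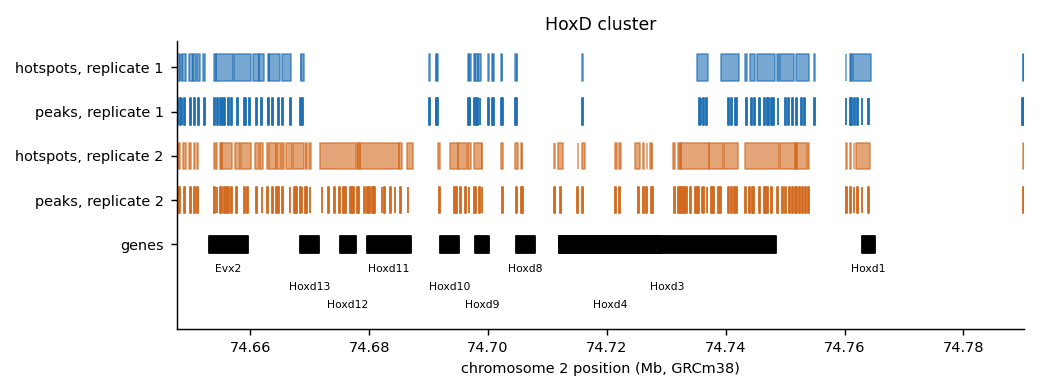
Peaks and hotspots of each replicate across the HoxD cluster, drawn to scale against position on chromosome 2 (Mb, GRCm38), with genes as black bars below. Replicate 1 (blue) has no peak over Hoxd12 and Hoxd11, where replicate 2 (orange) has wide hotspots, and the cluster holds 54 peaks in replicate 1 and 103 in replicate 2.

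Markers of other cell types that the tissue could hold differed from one another. Neural crest and head mesenchyme genes had 19 of 20 open promoters (adjusted p = 0.00303, Fisher's exact test; 0.000143 within CpG tertiles) and a median of 11.75 distal peaks, above all random lists. Foxc2 had 60 and 46 distal peaks, Tfap2a 49 and 41 and Msx2 32 and 29, while Sox10, a marker of migrating crest, had 7 and 8, no peak at its main TSS and one at another TSS in both replicates. With the shorter variable-width peak list the promoter call of this list was lost (adjusted p = 0.299, Fisher's exact test). Endothelial genes had 11 of 17 open promoters (adjusted p = 1, Fisher's exact test) and a median of 8 distal peaks, at the 99.3 percentile of random lists, led by Fli1 (19 and 20), Flt1 (16 and 20) and Ramp2 (15 and 20). Without replicate 2 this percentile was 96.7, inside the 95% range. Cdh5 and Egfl7 had no peak at their main TSSs in either replicate, and Egfl7 had one at another TSS in both.

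Erythroid promoters were open in 4 of 17 cases (adjusted p = 0.00303, Fisher's exact test), and the median of this list, 2.5 distal peaks, lay at the 49.2 percentile. The promoter difference turned around within CpG tertiles without passing the threshold (odds ratio 1.74, adjusted p = 0.514, exact test). Gata1, the erythroid master regulator, had no promoter peak in either replicate, and Epor and Epb42 had one in both. Macrophage and microglia promoters were open in 2 of 16 cases (adjusted p = 0.000297, Fisher's exact test; 0.514 within CpG tertiles), at Cd68 and P2ry12. The macrophage median of 6 distal peaks lay at the 98.6 percentile and dropped inside the 95% range with no matching (90.8) and with 1 member per locus (97.3), where the neighbouring genes C1qa, C1qb and C1qc count once. Mature glia genes had 7 of 15 open promoters (adjusted p = 0.355, Fisher's exact test) and a median of 8 distal peaks, at the 99.4 percentile. S100b had 7 distal peaks in replicate 1 and 28 in replicate 2, and 7 and 5 after removal of dense stretches of weak peaks, an alternative added after seeing the data.

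Liver and germ line genes were open at 2 of 18 promoters in each list (adjusted p = 8.87e-05 for both, Fisher's exact test). Both calls held within CpG tertiles, with adjusted p = 0.00724 for liver and 3.90e-06 for germ line in the exact test. Apob and Trf carried the open liver promoters and Spata18 and Tdrd1 the open germ line ones. Alb, the main liver secretory gene, had no promoter peak and 4 and 6 distal peaks. The liver median of 5 and the germ line median of 6 distal peaks lay at the 88.3 and 94.6 percentiles. With a 20 kb window the liver list rose above the 95% range (median 2.5, 98.7 percentile). Heart and skeletal muscle genes had 7 of 18 open promoters (adjusted p = 0.0756, Fisher's exact test), yet a median of 10.25 distal peaks, above all random lists. The transcription factors Hand2 (61 and 67), Gata4 (70 and 31) and Tbx5 (50 and 46) led this list. Its promoters passed the threshold as open less often with the longer and the shorter variable-width list (odds ratios 0.290 and 0.320, adjusted p = 0.0194 and 0.0442) and with any annotated TSS (0.340, adjusted p = 0.0359, Fisher's exact test), but not within CpG tertiles (1.09, adjusted p = 1). Myod1, which drives skeletal muscle fate, had 12 and 13 and a promoter peak in both replicates. Epithelial genes had 11 of 16 open promoters (adjusted p = 0.839, Fisher's exact test) and a median of 7.75 distal peaks at the 98.5 percentile, inside the 95% range with a 20 kb window (96.9), with a 100 kb window (94.5), without replicate 1 (96.2), and with CpG-poor distal peaks only (92.4) or 1 member per locus (97.3), the last 2 added after seeing the data.

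Housekeeping and cell cycle genes had open promoters without a crowd of distal peaks. All 20 housekeeping promoters and all 20 cell cycle promoters were open (adjusted p = 0.000314 for both, Fisher's exact test; 0.102 and 0.807 within CpG tertiles). Their medians of 6 and 7 distal peaks lay at the 76.3 and 91.5 percentiles. With no matching the cell cycle list lay at the 97.8 percentile, above the 95% range. Actb had 11 and 17 distal peaks and Mcm2, a replication licensing factor, 19 and 25. Across the 20 lists, 8 had open promoters more often than other genes and 4 less often. Within CpG tertiles these numbers were 2 and 3, with the shorter variable-width peak list 8 and 7, and with any annotated TSS 9 and 5. With the shorter list neuronal differentiation genes passed as open more often and posterior Hox, mature glia and heart genes as open less often. At distal peaks, 15 lists had more than the 95% range of random lists while 0 had fewer.

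**Figure D2:**
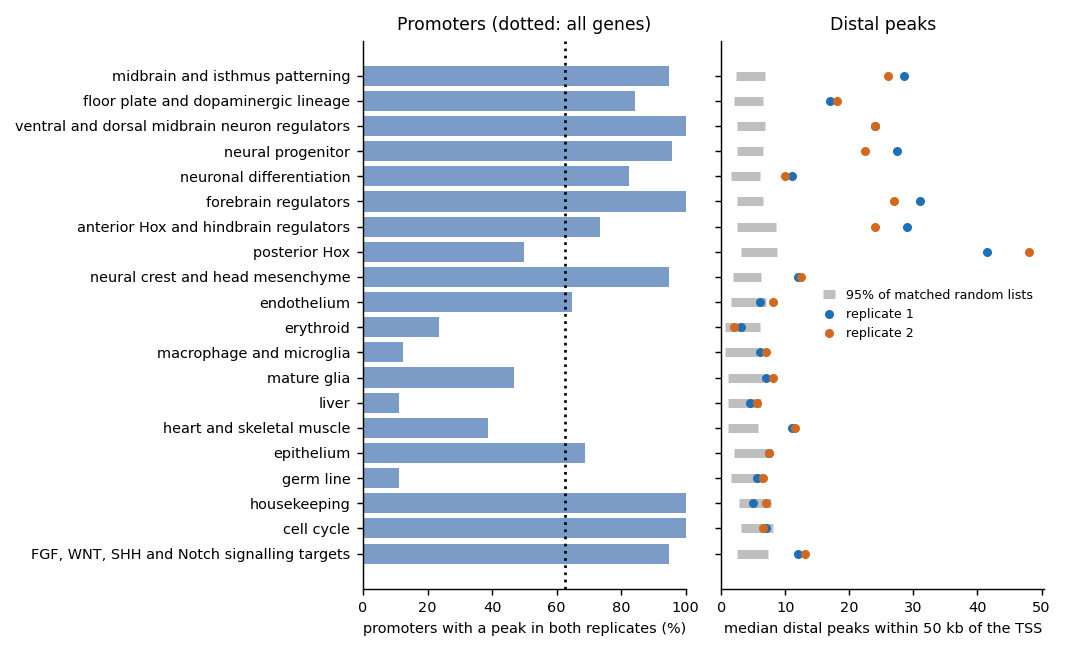
Left, percent of promoters with a peak in both replicates for each of the 20 gene lists, with the share of all genes, 62.7%, as a dotted line. Right, median number of distal peaks within 50 kb of the TSS per replicate (points) beside the 95% range of 10000 matched random lists (grey bars). The bars are for the mean of both replicates, so points and bars are not the same measure. Posterior Hox genes lie farthest right. Erythroid, liver, germ line, housekeeping and cell cycle genes lie within the range, as does the endothelial point of replicate 1.

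Promoters as a whole followed their CpG content. In both replicates 13685 of 21815 protein-coding genes had a promoter peak, 62.7%, with 63.6% in replicate 1 and 64.8% in replicate 2, and 643 genes had one in a single replicate. The share was 7.36% in the tertile of genes with the fewest CpGs, 82.1% in the middle tertile and 98.7% in the tertile with the most. Olfactory receptor genes, used by sensory neurons of the nose, had 6 open promoters of 1133, and vomeronasal receptor genes 2 of 328.

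By location, peaks were concentrated at TSSs. TSS-proximal peaks made up 23.4% ± 3.78 (SD, n = 2) of peaks, 26.1% in replicate 1 and 20.8% in replicate 2, beside 2.03% of the genome, 11.5-fold. Other exons held 4.36% ± 0.129, introns 31.9% ± 0.877 and intergenic sequence 40.3% ± 2.78 (SD, n = 2), beside 2.36%, 35.4% and 60.2% of the genome. The median score of TSS-proximal peaks was 228 against 80 for distal peaks in replicate 1, and 397 against 104 in replicate 2, so the ratio was 2.85 in replicate 1 and 3.82 in replicate 2.

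Replicates were then compared peak by peak. Of the peaks of replicate 1, 59.7% (95% Wilson interval 59.44 to 59.98) overlapped a peak of replicate 2, and 50.7% (50.44 to 50.96) of the peaks of replicate 2 overlapped one of replicate 1. Random placement gave 1.61% and 1.35%. TSS-proximal peaks were shared in 60.9% and 66.0% of cases and distal peaks in 59.3% and 46.7%. Across 73130 pairs of shared peaks, the scores of the replicates had a Spearman correlation of 0.850 and a Pearson correlation of the log2 scores of 0.864; these are correlations across peaks, which are not independent replicates. Sharing at 50% reciprocal overlap was 41.8% and 36.4%.

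**Figure D3:**
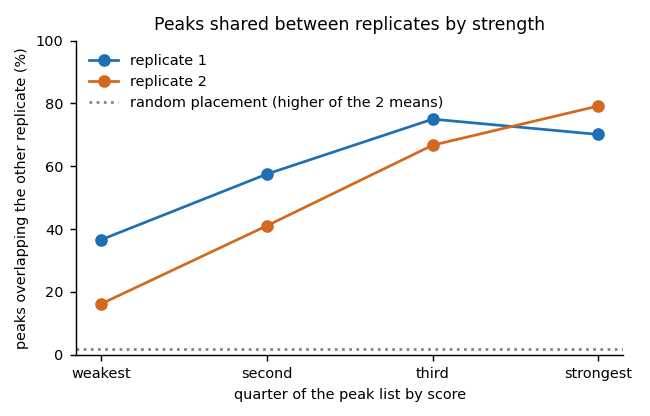
Percent of each replicate's peaks that overlap a peak of the other, with each list split by score into 4 equal parts from weakest to strongest. In replicate 1 the share runs from 36.6% to 75.02% and 70.1% in the upper parts, in replicate 2 from 16.1% to 79.2%, and the higher of the 2 means of random placement (dotted) is 1.61%.

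The sequence of distal peaks was compared with that of their flanks in 53662 windows of shared distal peaks and 63743 flank windows. The binding consensus of CTCF, the insulator protein, was in 6.91% of peaks and 0.0439% of flanks (odds ratio 169). REST, the repressor of neuronal genes, had 74 matches in peaks and 0 in flanks, at least 29.3-fold more, and RFX had 101 and 0, at least 39.99-fold, both taken against a floor of 3 counts in the flanks. With GC-matched flanks the counts were 34 and 65 against 0, at least 11.3-fold and 21.7-fold more. Among neural factor classes, the ASCL E-box (odds ratio 4.22), ZIC/GLI (3.52), SOX (1.71) and the proneural E-box (1.40) were more frequent in peaks. The ZIC/GLI and proneural consensuses overlap that of CTCF in sequence. Without windows that held a CTCF consensus, an alternative added after seeing the data, the ZIC/GLI odds ratio was 3.15 (437 of 49952 peaks, adjusted p = 2.79e-41, Fisher's exact test) and the proneural one 1.26 (adjusted p = 1.21e-08, Fisher's exact test). In all, 16 of 30 consensuses were more frequent and 6 less frequent at an adjusted p under 0.05 (Fisher's exact test). The less frequent ones were LMX1/LHX (0.275), homeodomain TAAT (0.411), GATA (0.612), FOX (0.752), RUNX (0.822) and OTX (0.857). Against flanks of matched GC content, the odds ratios of all of these but GATA rose above 1.

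Peaks held 53.0% GC and flanks 43.8%. With 34084 windows each at matched GC content, homeodomain TAAT (odds ratio 1.39, adjusted p = 1.88e-10), FOX (1.36, adjusted p = 4.51e-07) and POU (2.07, adjusted p = 2.43e-16) were more frequent in peaks by Fisher's exact test. OTX (1.02), LMX1/LHX (1.13) and RUNX (1.15) no longer passed the threshold. GATA stayed less frequent (0.797, adjusted p = 0.00984, Fisher's exact test). SOX (1.91), ASCL E-box (1.963), ZIC/GLI (1.84), proneural E-box (1.22), TEAD (1.36) and TCF/LEF (1.42) stayed more frequent, while NRF1 (from 6.38 to 1.55), ETS (from 2.31 to 1.26), CREB (from 2.79 to 1.46) and GRHL (from 2.05 to 1.69) lost their calls. The GC-matched windows still held a CTCF consensus in 7.40% of peaks. GC matching and removal of CTCF windows were not combined. Whether ZIC/GLI and the proneural E-box keep their calls under both was not tested.

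**Figure D4:**
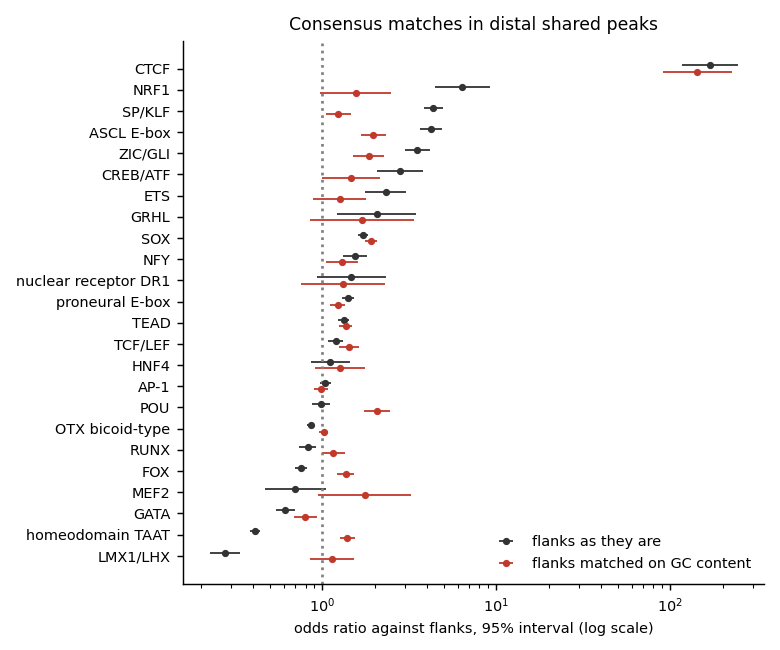
Odds ratio of consensuses in distal shared peaks against flanks (log scale, 95% interval), with flanks as they are (black) and flanks matched on GC content (red). Consensuses with few matches in peaks or none in flanks (REST, RFX, YY1, NFI, HNF1 and PAX2/5/8) are not drawn. CTCF stands at 169 and 143, and homeodomain TAAT moves from 0.411 to 1.39.

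Footprints overlapped consensus matches of several factor classes, although binding itself was not measured. Among consensus matches in shared peaks, a footprint of both replicates overlapped 77.3% of 934 NRF1 matches, 75.9% of 3850 CTCF matches, 66.5% of 430 CREB matches and 64.0% of 89 REST matches. In replicates 1 and 2 taken singly, the shares were 80.9% and 87.9% for NRF1 and 76.9% and 96.3% for CTCF. For CREB they were 71.6% and 81.2%, and for REST 64.0% and 98.9%. Neural factor classes had fewer, with 17.9% for the proneural E-box, 16.3% for ZIC/GLI, 9.23% for SOX, 6.52% for OTX and 3.90% for homeodomain TAAT. These shares do not rank the classes by binding. Any overlap counted, so a longer consensus was hit more easily, and no share for random positions was set beside them. Footprints covered 9.19% and 13.3% of the bases of 150 bp peaks in replicates 1 and 2. TSS-proximal and distal peaks were pooled, which differ in score. Against positions shifted by 50 bp in the same peaks, 9 of 30 consensuses were more frequent at footprints in both replicates. CTCF had odds ratios of 6.63 and 5.97 in replicates 1 and 2, REST 13.2 and 6.43, ZIC/GLI 1.54 and 1.86 and the proneural E-box 1.503 and 1.65, whereas FOX was less frequent, at 0.639 and 0.526. In peaks without a CTCF consensus, also added after seeing the data, 9.77% of 573 ZIC/GLI matches and 12.4% of 1492 proneural matches had a footprint of both replicates. The proneural odds ratios there were 1.28 and 1.46, both past the threshold. That of ZIC/GLI was 1.23 in replicate 1, where the call was lost (adjusted p = 0.126, Fisher's exact test), and 1.53 in replicate 2 (adjusted p = 1.84e-07, Fisher's exact test). SOX (0.992 and 1.23) and OTX (1.05 and 1.20) passed the threshold in replicate 2 alone. Of all footprints, 37.0% of those in replicate 1 and 30.9% of those in replicate 2 overlapped one of the other replicate, against 16.7% and 12.3% for random positions inside peaks. The random positions were spread evenly over all 150 bp peaks, of which 64.9% and 70.4% held a footprint. The excess thus mixes which peaks hold footprints with where in them footprints lie. The 150 bp peaks held 49.8% and 59.9% of footprints, and the hotspots 99.7% and 99.1%.

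Hotspots and the cut-rate files covered more sequence than peaks. Hotspots of the replicates shared 62.3% of their joint length, and 99.99% of the peaks of replicate 1 and 99.998% of those of replicate 2 lay inside hotspots. The −log10 q-value stood at its cap of 100 for 51 hotspots of replicate 1 and 3144 of replicate 2. Positions with a cut-rate FDR of at most 0.05 covered 52.5 and 54.9 Mb in the first alignment, with 62.2% of the joint length shared. At that FDR, promoters of midbrain patterning genes were covered in 19 of 20 cases (adjusted p = 0.00666, Fisher's exact test), forebrain regulators in 21 of 21, macrophage genes in 2 of 16 and liver genes in 3 of 18. At an FDR of at most 0.001, added after seeing the data, neural crest and mesenchyme promoters were covered in 15 of 20 cases and lost their call (adjusted p = 0.287, Fisher's exact test). Midbrain patterning promoters were covered in 18 of 20 cases there (odds ratio 5.54, adjusted p = 0.0161) and heart promoters in 5 of 18 (odds ratio 0.236, adjusted p = 0.0102, Fisher's exact test).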

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

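Among the alternatives below, the removal of dense weak peaks, CpG-poor distal peaks only, 1 member per locus, the posterior Hox promoter test with 1 replicate alone, a peak at any annotated TSS, windows without a CTCF consensus, the second alignment and the cut-rate FDR of at most 0.001 were chosen after seeing the data. The number of gene lists with more distal peaks than the 95% range of random lists stayed within 1.5 times the main number under all 11 alternatives, and the midbrain patterning list kept its call in each. Of 220 distal comparisons of single lists, 210 kept their side of the threshold, 8 lost their call and 2 gained one. The gains were liver with a 20 kb window (98.7 percentile) and cell cycle with no matching (97.8). Of 300 comparisons of single consensuses, 276 kept a call in its direction or stayed without a call, whatever their direction. No paired analysis was possible because there is 1 group. Read depth is not given, so no interval here covers sampling of reads.

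The share of peaks overlapping the other replicate, in replicates 1 and 2, was 72.3% and 60.1% with the longer variable-width list, 77.8% and 62.1% with the shorter list, 59.1% and 57.5% with equal numbers of peaks, 41.8% and 36.4% at 50% reciprocal overlap, and 77.1% and 63.9% against hotspots. It was 53.8% in replicate 2 without dense weak peaks. The Spearman correlation was 0.872, 0.830, 0.846 and 0.841 with the longer list, the shorter list, equal numbers and reciprocal overlap. TSS-proximal peaks made up 33.6% with the shorter list, 16.8% within 500 bp and 30.03% within 2 kb of a TSS, and 20.8% to 26.1% with a replicate left out. Open promoters made up 61.0% with the shorter list, 64.5% within 1000 bp, 63.8% with hotspots, 65.2% with any annotated TSS, and 63.6% to 64.8% with a replicate left out.

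With the shorter list 7 gene lists were open less often in place of 4. Within CpG tertiles 2 lists were open more often in place of 8, the midbrain patterning list had an odds ratio of 27.1 past no threshold (adjusted p = 0.145, exact test), and the erythroid list turned to 1.74. The 4 lists with every promoter open gave no odds ratio there. With the shorter list the consensus of AP-1 turned to an odds ratio of 0.884 and that of TCF/LEF to 0.956. With GC-matched flanks 1 consensus was less frequent in place of 6, and homeodomain TAAT (1.39), OTX (1.02), LMX1/LHX (1.13), POU (2.07), FOX (1.36) and RUNX (1.15) turned around, where the matching itself removes the difference in GC content. Shared footprints fell to 21.4% and 18.9% at reciprocal overlap and stood at 49.0% and 38.1% inside shared peaks. With a replicate left out, 10 to 14 consensuses were more frequent at footprints. The shared length of cut-rate positions was 62.2% in the second alignment and 64.1% at an FDR of at most 0.001. The cause of the other changes was not tested.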

Other observations

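Of the tests in this part, the comparison of the midbrain list with other lists, also with 1 member per locus, the posterior Hox promoter test with 1 replicate alone, the split of distal peaks by CpG content, the score ratio, the removal of dense weak peaks, the definition of dense stretches, their comparison with peaks of the same score and the GC content over 150 bp were chosen only after the result was seen, and so were the readings of the posterior Hox odds ratio and of the midbrain list's rank ratio given below.

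Midbrain regulators had more distal peaks than genes of most non-neural lists. Their median of 27 exceeded that of neural crest and mesenchyme genes by 15.25 (adjusted p = 0.00843), of endothelial genes by 19 (adjusted p = 0.00171) and of erythroid genes by 24.5 (adjusted p = 0.000418), in two-sided permutation tests with 100000 permutations and adjustment over 19 lists. Unlike the random lists above, these tests did not match genes on CpG ratio or on the number of TSSs nearby. With 1 member per locus these differences were 13.5 (adjusted p = 0.0289), 18 (adjusted p = 0.00149) and 22.5 (adjusted p = 0.00149, permutation tests). The difference from housekeeping genes was 21 (adjusted p = 9.5e-05, from a raw p of 1e-05, the smallest that 100000 permutations can give). The difference from heart and skeletal muscle genes was 16.75 and missed the threshold (adjusted p = 0.0509, permutation test). With 1 member per locus it was 16.5 and passed (adjusted p = 0.0428, permutation test). The difference from forebrain regulators was -2 (adjusted p = 0.752) and that from neural progenitor genes 1.75 (adjusted p = 0.752, permutation tests). For anterior Hox and hindbrain regulators it was 3.5 (adjusted p = 0.650, permutation test). Posterior Hox genes exceeded midbrain regulators, with a difference of -16.5 (adjusted p = 0.00171, permutation test), but these genes share clusters and peaks. With 1 member per locus, 19 midbrain loci stood against 4 Hox loci with a difference of -18.75, which missed the threshold (p = 0.0463, adjusted p = 0.0628, exact permutation test over all 8855 splits).

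Among genes outside the lists, some with many distal peaks were chosen after their values were seen. Nr2f2, a nuclear receptor gene on chromosome 7, had 64 in each replicate, and Zic4, next to Zic1 on chromosome 9, had 59 and 66. Hoxd8, in the HoxD cluster, had 41 and 81, and Cbx8 had 62 and 57. Evx1, beside the HoxA cluster, had 57 and 52, Foxf1 had 61 and 47, Nr2f1 had 55 and 50, and Pdx1, a regulator of the pancreas, had 61 and 41. These counts were the same after dense weak peaks were removed.

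Genes of several other body regions and cell types lay among crowds of distal peaks. Erythroid, liver and germ line genes did not (49.2, 88.3 and 94.6 percentiles), although liver genes passed with a 20 kb window (98.7). Macrophage and epithelial genes lost their call with 1 member per locus (97.3 each). CpG-rich sequence open in any tissue is a candidate explanation, but with CpG-poor distal peaks only the medians of the posterior Hox, forebrain and heart lists were 21.5, 14.5 and 7.75, at the 100 percentile of random lists whose upper bounds were 6.25, 5.5 and 4.25, which argues against it as the whole cause, while the CpG-rich peaks left out (medians 22.5, 11 and 1.25 against upper bounds of 2.5, 1.5 and 1) leave it open as part of it. At promoters it was met in part: every forebrain promoter was open, so its exact p of 0.0900 within CpG tertiles is the smallest possible and CpG content and regulation cannot be told apart for that list. The posterior Hox odds ratio of 0.123 came from replicate 1 and was 0.568 in replicate 2 alone, below 1 as CpG content alone allows, so the explanation cannot be told apart from closure of these promoters there either. Cells of other types in the tissue may account for the crowds around neural crest and mesenchyme genes, at the 100 percentile. They may also account for those around endothelial genes, at the 99.3 percentile, although not without replicate 2 (96.7). That met the bound set beforehand, which needed 1 of these lists or the erythroid or macrophage list above the 95% range. But the percentiles restate the crowds that raised the explanation. With 1 group it cannot be told apart from other biological causes.

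The replicates differed in the spread and the ranks of peak scores. Deeper sequencing would multiply all scores alike, but the ratio of the 99th percentile to the median of shared peaks was 2.36 times higher in replicate 2 (10.7 against 4.51), which argues against depth as the whole cause. For peaks that lie in different places, a separate matter, base composition of what each library recovered cannot be told apart from other causes: over 500 bp the mean GC contents of distal peaks in 1 replicate alone differed by 0.192 points (48.8% and 48.6%), but over the 150 bp of the peaks by -2.53 points (49.6% and 52.1% in replicates 1 and 2), between the bounds set beforehand of 1 and 3 points. For a different share of another cell type, the mesenchyme list had a median log2 rank ratio of -0.36, outside the range of random lists as that explanation needs, but the midbrain list lay below its range too (-0.32), as did 11 of 20 lists in all, so a different cell share and a technical shift of ranks cannot be told apart with 2 samples. The 2 instruments named for replicate 2 alone stay open too.

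Replicate 2 held 629 dense stretches of weak peaks with 9067 peaks, 6.45% of its list, and replicate 1 held 77 with 736 peaks. The longest, on chromosome 14 from 65870137 to 65919170 near Ccdc25, had 75 such peaks where replicate 1 had 2 peaks. A threshold of the caller that fell over these stretches is a candidate explanation, and 3.22% of their distal peaks overlapped replicate 1, but so did only 5.83% of other distal peaks of the same score, and 25.5% held a footprint against 16.7% of those. Their GC excess over flanks was 0.569 times that of all other distal peaks (95% interval 0.544 to 0.594) and 0.709 times that of peaks of the same score, above the bound set beforehand for such a cause. The other bound set beforehand, a low overlap with replicate 1, was met (3.97% of all dense weak peaks). Dense stretches of replicate 1 had a like GC ratio of 0.572. Calls centred on local maxima of cuts could hold a GC excess under any threshold, so this test cannot decide. What made the stretches of replicate 2 stays open, and 8 of them had been looked at, without their GC content, before the bounds were set.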
